A study of Mus musculus with 6 samples.

How the data were processed

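RNA was measured in the motor cortex of SOD1G93A mice, a transgenic line that carries a mutant human SOD1 and is used as a model of amyotrophic lateral sclerosis. The mice were sampled at day 120 either as controls or after ultrasound treatment, which the series names low-intensity pulsed ultrasound. There were 3 control and 3 ultrasound libraries, numbered 1 to 3 in the labels. Each label names a mouse, but nothing used here says in more detail that the libraries came from separate animals, so the p-values measure the spread between these libraries. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, the second cDNA strand was marked with dUTP and removed, and the libraries were sequenced as read pairs on an Illumina NovaSeq instrument.

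The authors deposited raw counts and FPKM values for 33182 genes, 1 column of each kind per library. FPKM values are scaled by the authors to transcript length and to the library's number of mapped fragments, per the file headers. The submitters' processing notes list cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR, with the build mm10, without giving each its role. The tool that made the counts, its use of strand and its treatment of reads that match several genes are not given in the sources used here. Values of near-identical genes, such as ribosomal protein genes with processed pseudogenes, and of overlapping genes are therefore uncertain. Among the gene identifiers, 32701 were shared with GENCODE M21 on GRCm38, but only 656 of these had the same start and end there, so coordinates are given as the table lists them, and the annotation they follow is not given in the sources used here. Whether reads of the human transgene were counted under the mouse Sod1 gene is likewise not given. Another 12 columns of per-library values were not used.

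Total counts per library ranged from 38202541 to 60088636. For 12627 genes with at least 100 counts in every library, the ratio of the deposited FPKM to the counts was divided by the same gene's ratio in control 1. In each other library, this relative ratio lay within 1% of the library median for at least 99.45% of the genes. Between libraries, both units therefore carry the same measurements of a gene, up to 1 factor per library. No pair of libraries was identical, and the chi-square statistic per gene was far above that of sampling noise for each pair. Counts of PCR-amplified reads without molecular identifiers are not independent molecules.

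Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, which left 15740. The counts were fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the robust option and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design fixed before the data were examined named this test for a table with counts, and a limma 3.58.1 fit of log2(FPKM + 0.5) for one without. With counts, that limma fit was to be an alternative. Log2 fold changes are ultrasound minus control throughout, with the standard error (SE) from the fit. The number of genes with an unadjusted p under 0.05 and at least a 2-fold change was counted as well. A set of 42 gene lists for cell types, brain regions and processes, holding 646 symbols of which 645 were found, was fixed before the data were examined. Each list was tested with camera of limma on log2(FPKM + 0.5) with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. The GO and KEGG terms that the table pairs with genes were tested in the same way where they held 15 to 300 tested genes, which gave 514 terms. Differences between library medians of a list were tested with a two-sided exact permutation test, which cannot fall below 0.1 with 3 libraries against 3.

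Genes named in the text followed a rule set in advance. It took up to 15 genes per direction that passed the threshold with groups that did not overlap, filled up in order of unadjusted p from genes with a mean FPKM of at least 1 and non-overlapping groups, which are said not to pass. Predicted genes, pseudogenes and unnamed loci were skipped, 4 in all. The rule also took the members of each list with the smallest p, and a fixed set that included Sod1, Gfap, Fos, Bdnf, Piezo1 and Ttr. Xist fell below the FPKM minimum and was not tested, and a few list members are not reported here. Other members of fixed lists, and the olfactory, neutrophil and cytokine genes, were named after their values were seen.

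The gene test was tested on simulated counts drawn from the real means, library sizes and dispersions of 15740 genes, 200 of them changed. It recovered 0 of 67 genes changed 1.5-fold, 23.9% of 67 genes changed 2-fold and 74.2% of 66 genes changed 4-fold, with 7 calls among the unchanged genes. In simulated CPM values, camera with the preset correlation called 5 of 5 sets of 15 genes shifted by 0.3 on the log2 scale and 0 of the others, and with an estimated correlation it called 0 of the 5. The simulated genes were drawn independently of each other, whereas the 8 lists that passed in the real data had estimated correlations of 0.023 to 0.885. The simulation therefore does not show how often the preset correlation gives false calls in such lists. Alternatives covered the pseudocount, the filter, the scaling, library weights, the empirical Bayes step, a replicate block, each library left out in turn, DESeq2 1.42.0, and settings added after the data were seen.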

Results

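The series asked how low-intensity pulsed ultrasound affects the motor cortex of SOD1G93A mice. Gene expression was compared between 3 control and 3 ultrasound-treated libraries at day 120. The control libraries held 55686084, 60088636 and 38202541 counts and the ultrasound libraries 44013220, 45885619 and 42726633. The 18S ribosomal RNA gene took 1.67%, 0.561% and 4.68% of the counts in controls 1 to 3 and 0.655%, 9.18% and 1.13% in ultrasound libraries 1 to 3.

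Phc3, a subunit of the Polycomb repressive complex, rose after ultrasound and was the only gene of 15740 to pass the threshold. Its mean was 0.565 ± 0.0795 FPKM (SD, n = 3) in controls and 3.97 ± 0.513 FPKM (SD, n = 3) in ultrasound libraries. The log2 fold change was 2.84 (SE 0.17), with an adjusted p of 0.00284 from the edgeR quasi-likelihood test. Phc3 had 718, 588 and 420 counts in the controls and 3608, 3026 and 3623 in the ultrasound libraries, so each ultrasound library lay above each control. The table places the gene (ENSMUSG00000037652, protein-coding) on the minus strand of chromosome 3 at 30953520 to 31023554. The call held with each library left out in turn, with adjusted p up to 0.0403 in edgeR, but limma fits of log2 FPKM did not pass Phc3, and its adjusted p ranged from 1.31e-45 in DESeq2 to 0.129 over the alternatives that tested it.

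Among genes with higher ultrasound values that did not pass in edgeR, Shc3 had the smallest p. Shc3, a neuronal adaptor of receptor tyrosine kinases, averaged 4.74 ± 0.821 FPKM in controls and 10.7 ± 0.777 FPKM in ultrasound libraries (SD, n = 3), with a log2 fold change of 1.22 (SE 0.17) and an edgeR adjusted p of 0.532. Ube2a, a ubiquitin-conjugating enzyme, had a log2 fold change of 1.31 (SE 0.20), and Phlpp2, a phosphatase that acts on AKT, one of 1.17 (SE 0.18), both with the same adjusted p. Azin1, the antizyme inhibitor of polyamine metabolism, had a log2 fold change of 0.76 (SE 0.12), and Hk1, the main brain hexokinase, one of 0.48 (SE 0.10). Slc6a17, a vesicular amino acid transporter of synapses, averaged 27.9 ± 3.22 FPKM in controls and 47.5 ± 7.62 FPKM in ultrasound libraries. The log2 fold changes of Sh3kbp1, Nhsl1, Dnase2a, Bcl7b, Ncam2, Rap1gds1, Ubap1 and Degs1 lay between 0.61 and 1.58. None of these 14 genes passed in edgeR, while DESeq2 passed Shc3, Phlpp2, Ube2a, Azin1, Sh3kbp1, Slc6a17, Nhsl1, Hk1 and Dnase2a.

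Among genes with lower ultrasound values, Lrrc47 came closest to the threshold. It averaged 15.9 ± 0.977 FPKM in controls and 5.97 ± 1.28 FPKM in ultrasound libraries (SD, n = 3), with a log2 fold change of -1.38 (SE 0.17) and an edgeR adjusted p of 0.272. Hinfp, a transcription factor of histone genes, had a log2 fold change of -1.50 (SE 0.23) and an adjusted p of 0.532. Rpl17, a protein of the large ribosomal subunit, had a value of -0.86 (SE 0.19), Hdac7, a histone deacetylase, -0.62 (SE 0.14), and Prpf39, a splicing factor, -0.59 (SE 0.13). The host transcript Mir124a-1hg of the neuronal microRNA miR-124 averaged 55.9 ± 9.01 FPKM in controls and 37.8 ± 5.24 FPKM in ultrasound libraries. Mxd4, Pip5kl1, Dusp16, Trafd1, Zfp14 and Pgap6 had log2 fold changes from -1.10 to -0.52. None of these genes passed in edgeR with the main filter, while edgeR with no filter passed Lrrc47 and DESeq2 passed Lrrc47 and Hinfp. The remaining genes of this direction, Ciart, Per1 and Lcn2, are described with their lists.

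**Figure D1:**
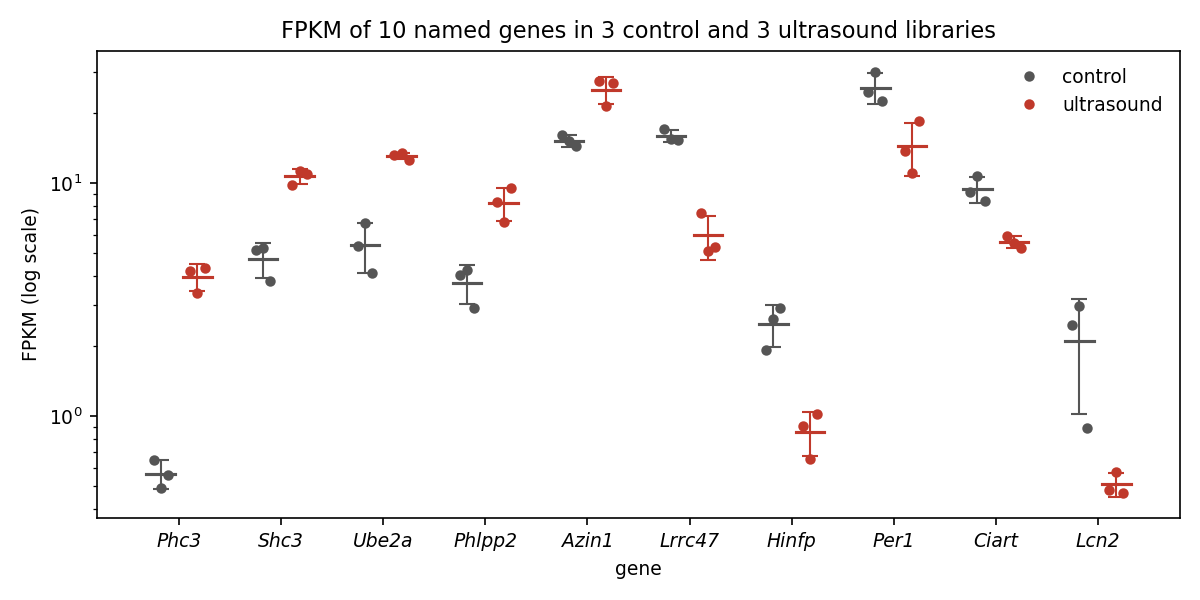
FPKM on a log scale for 10 named genes, with a point per library, a horizontal line at the group mean and bars of 1 SD (n = 3), grey for control and red for ultrasound. Phc3 lay at 0.489 to 0.648 FPKM in the controls and at 3.38 to 4.33 FPKM in the ultrasound libraries, and it was the only gene of the 10 to pass the threshold.

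Across all tested genes, 751 (4.77%) had an unadjusted p under 0.05, of which 386 were higher and 365 lower with ultrasound. At least a 2-fold change was also seen in 200 of these, 96 higher and 104 lower, a count not controlled for multiple testing. The groups did not overlap for 1697 genes (10.8%), where chance gives 10%. Without TMM scaling, in the limma fit of log2(FPKM + 0.5), 36.5% of the genes with an unadjusted p under 0.05 were higher, against 51.4% in edgeR. The number of genes past the threshold was 4 without control 2 and 4 without control 3, against 1 with all libraries, and 29 in DESeq2. Those without control 2 were Phc3, the pseudogene Gm12715 and 2 entries both named Septin2, with 2 of the 4 higher and 2 lower. Those without control 3 were Phc3, Nfe2l1, Phf24 and the pseudogene Rpl35a-ps3.

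Among the members of the fixed lists, the clock genes Ciart and Per1 had the smallest p-values in edgeR, followed by Lcn2. Per1, a core repressor of the clock, averaged 25.7 ± 3.89 FPKM in controls and 14.4 ± 3.71 FPKM in ultrasound libraries (SD, n = 3), a log2 fold change of -0.80 (SE 0.19). Ciart, another clock repressor, had a log2 fold change of -0.71 (SE 0.17), and Nr1d1, the nuclear receptor REV-ERB alpha, one of -0.77 (SE 0.21). These 3 of 16 tested members of the circadian and glucocorticoid list passed when adjusted over the list alone, with adjusted p of 0.0224 for Per1 and Ciart and 0.037 for Nr1d1 in edgeR, and 0 passed when adjusted over all genes. Per2, Fkbp5 and Tsc22d3 had log2 fold changes of 0.04, 0.07 and -0.07, and the list as a whole did not pass, with a median of -0.01 and a camera adjusted p of 0.482. In the reactive astrocyte list, Lcn2, an acute-phase lipocalin, passed when adjusted over the list alone (adjusted p = 0.0381 in edgeR), with 411, 534 and 102 counts in the controls and 64, 79 and 61 in the ultrasound libraries. Lcn2 is also a neutrophil gene, and the neutrophil markers S100a8, Retnlg and Mmp9 were likewise higher in controls 1 and 2 than in the other 4 libraries. Gfap, the intermediate filament of astrocytes, averaged 35.9 ± 12.4 FPKM in controls and 34.8 ± 7.47 FPKM in ultrasound libraries, and the list had a median log2 fold change of -0.05 and a camera adjusted p of 0.591. No member of the other 40 lists passed in edgeR with all 6 libraries with either adjustment. Adjustment over a list alone does not correct for the 42 lists examined, so members of some lists can pass by chance. Adjusted over all genes, DESeq2 passed Lcn2 and Chil3, an anti-inflammatory mediator.

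Of the 42 lists, 8 ranked higher with ultrasound than the other tested genes in camera with the preset correlation, and none ranked lower. With an estimated correlation 0 of the 42 passed. In the unfolded protein response list, 15 of 17 tested members were higher, among them the chaperone Hspa5 (log2 fold change 0.44, SE 0.21), the disulphide isomerases Pdia4 (0.42, SE 0.16) and Pdia6 (0.38, SE 0.15), and the secreted factor Manf (0.38, SE 0.17). The list's median log2 fold change was 0.28 and its adjusted p was 0.000575 (adjusted p = 0.799 with an estimated correlation). Of 14 striatal genes 12 were higher, with a median of 0.42 and an adjusted p of 0.000575 (adjusted p = 0.799 with an estimated correlation), including Pde10a (1.13, SE 0.49) and the dopamine receptors Drd1 (0.53, SE 0.57) and Drd2 (0.45, SE 0.75). Layer 5 projection neuron genes were higher in 9 of 11 cases, with a median of 0.31 and an adjusted p of 0.0175 (adjusted p = 0.799 with an estimated correlation), led by Ldb2 (1.29, SE 0.41) and Etv1 (0.60, SE 0.23). The synaptic vesicle and postsynaptic density list had 12 of 19 members higher, a median of 0.14 and an adjusted p of 0.0196 (adjusted p = 0.799 with an estimated correlation), with the scaffolds Shank3 (0.51, SE 0.16) and Homer2 (0.60, SE 0.18). Of 17 glutamate receptor and transport genes 13 were higher, with a median of 0.14 and an adjusted p of 0.0230 (adjusted p = 0.799 with an estimated correlation), led by the NMDA receptor subunit Grin2b (0.65, SE 0.17) and the receptor Grm5 (0.43, SE 0.15).

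Glial and ventricular lists made up the rest of the 8. Oligodendrocyte precursor genes were higher in 9 of 10 cases, with a median of 0.20 and an adjusted p of 0.0175 (adjusted p = 0.799 with an estimated correlation), including Cspg4 (0.79, SE 0.28), Olig2 (0.44, SE 0.20) and Pdgfra (0.61, SE 0.28). Of 12 homeostatic microglia genes 9 were higher, with a median of 0.31, a mean of 0.07 and an adjusted p of 0.0196 (adjusted p = 0.799 with an estimated correlation), led by the purinergic receptor P2ry12 (0.80, SE 0.21) and Selplg (0.51, SE 0.18), while Cx3cr1 had -1.78 (SE 0.76). Of 8 choroid plexus and ependyma genes 7 were higher, with a median of 0.61 and an adjusted p of 0.0185 (adjusted p = 0.799 with an estimated correlation). Ttr, the thyroid hormone carrier made by the choroid plexus, was at 2.35, 1.63 and 3.88 FPKM in the controls and at 7.08, 12.7 and 235 FPKM in the ultrasound libraries. No single member of the 8 lists passed in edgeR with all 6 libraries, adjusted over all genes or adjusted over the list alone.

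**Figure D2:**
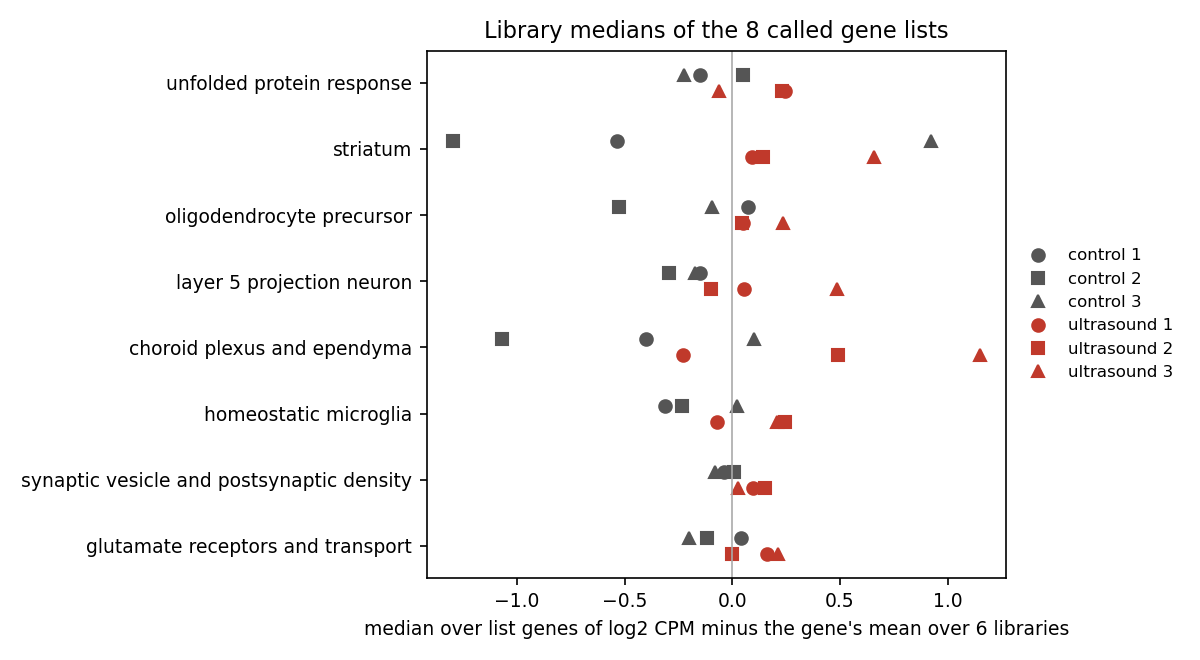
For each of the 8 lists, a point per library shows the median over the list's genes of log2 CPM minus the gene's mean over the 6 libraries, grey for control and red for ultrasound, with circles, squares and triangles for libraries 1, 2 and 3. The striatal medians were -0.54, -1.30 and 0.93 in controls 1 to 3 and 0.09, 0.14 and 0.66 in the ultrasound libraries, so the groups overlapped.

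Several of these lists moved with single libraries. The striatal median was -1.30 in control 2 and 0.93 in control 3, with an exact permutation p of 0.5 between groups, two-sided. Control 3 lay above each ultrasound library (0.09, 0.14 and 0.66), so against control 3 alone the direction was reversed. Layer 5 genes lay between -0.29 and -0.15 in the controls and between -0.10 and 0.49 in the ultrasound libraries, and the exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. It was also 0.1, with no overlap, for the synaptic vesicle and postsynaptic density list (controls -0.08 to 0.01, ultrasound 0.03 to 0.15). Outside the 8, it was 0.1 for calcium channels and the neurotrophic and heat shock lists, all higher with ultrasound. The apoptosis list, also at 0.1, was lower (controls 0.055 to 0.235, ultrasound -0.191 to 0.03). Chance alone gives groups of 3 that do not overlap in 10% of cases, so some of the 42 lists would separate in this way. Control 3 also held olfactory bulb transcripts, with Doc2g at 17.6 FPKM, Cdhr1 at 24.1 FPKM and Omp at 10.6 FPKM, where the other 5 libraries had at most 1.12, 2.14 and 0.216 FPKM. The number of lists past the threshold was 5 without control 2, 4 without ultrasound 3 and 12 without control 3. Of the 8 lists, the unfolded protein response passed with each library left out in turn but not without control 3 and ultrasound 2, the pair richest in 18S, and its library medians overlapped (controls -0.22 to 0.05, ultrasound -0.06 to 0.25, exact permutation p = 0.2). With single libraries left out, the other 7 each lost the threshold at least once: the striatal list without control 2, the oligodendrocyte precursor and layer 5 lists without control 2 or ultrasound 3, the choroid plexus list without control 1, control 2 or ultrasound 3, the synaptic list without control 3, ultrasound 1 or ultrasound 2, homeostatic microglia without control 1, control 2, ultrasound 2 or ultrasound 3, and the glutamate list without control 2, control 3, ultrasound 1 or ultrasound 3. Lists outside the 8 that passed with the preset correlation in at least 1 of these fits were activity-induced early genes, fibroblasts, complement and both cytokine lists (without control 3), blood (without control 3 or ultrasound 3), ribosomal proteins (without control 1 or ultrasound 2), neurotrophic factors (without control 1), excitatory neurons and axon growth (without control 2), myelin (without control 2 or ultrasound 2), and GABA receptors and sodium and potassium channels (without ultrasound 2). With all 6 libraries, these lists had adjusted p = 0.799 with an estimated correlation, except activity-induced early genes (0.854) and inflammatory cytokines and NF-kB targets (0.840). The fibroblast and ribosomal protein lists, which had adjusted p = 0.799 with an estimated correlation, passed with library weights as well.

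With all 6 libraries no list named for inflammation passed, and some neutrophil transcripts separated controls 1 and 2 from the other libraries. S100a9, a neutrophil calcium-binding protein, had 274, 607 and 8 counts in controls 1 to 3 and 12, 91 and 80 in the ultrasound libraries. Pro-inflammatory cytokines and NF-kB targets had 7 of 10 tested members lower, with a median log2 fold change of -0.07, a mean of -1.10 and an adjusted p of 0.576, and Icam1 (-1.19, SE 0.43) and Ccl3 had the smallest p. Ccl3 had 180, 166 and 0 counts in controls 1 to 3 and 4, 0 and 0 in the ultrasound libraries. Of 8 anti-inflammatory mediators 6 were lower, with a median of -0.28 and an adjusted p of 0.151, among them Socs3 (-0.84, SE 0.27). Chil3, in the same list, had 259, 226 and 3 counts in the controls and 4, 8 and 4 in the ultrasound libraries. Without control 3, both lists ranked lower with ultrasound, with camera adjusted p of 0.00735 for inflammatory cytokines and NF-kB targets (0.00735 to 0.933 over the alternatives) and 0.0165 for anti-inflammatory mediators (0.0165 to 0.891). Only the 2 controls rich in neutrophil transcripts remain in that fit, and with all 6 libraries these lists had adjusted p = 0.840 and adjusted p = 0.799 with an estimated correlation. Interferon response genes had a median of -0.25 (adjusted p = 0.454), with 9 of 10 lower. Complement and antigen presentation genes had a median of -0.07, a mean of 0.29 and an adjusted p of 0.436. Disease-associated microglia genes had a median of 0.11 (adjusted p = 0.434), and Lpl had a log2 fold change of 0.59 (SE 0.22). Infiltrating leukocyte genes had a median of -0.39 over 4 tested members although camera ranked them upward (adjusted p = 0.399). With no filter that list passed upward, and it had adjusted p = 0.799 with an estimated correlation.

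**Figure D3:**
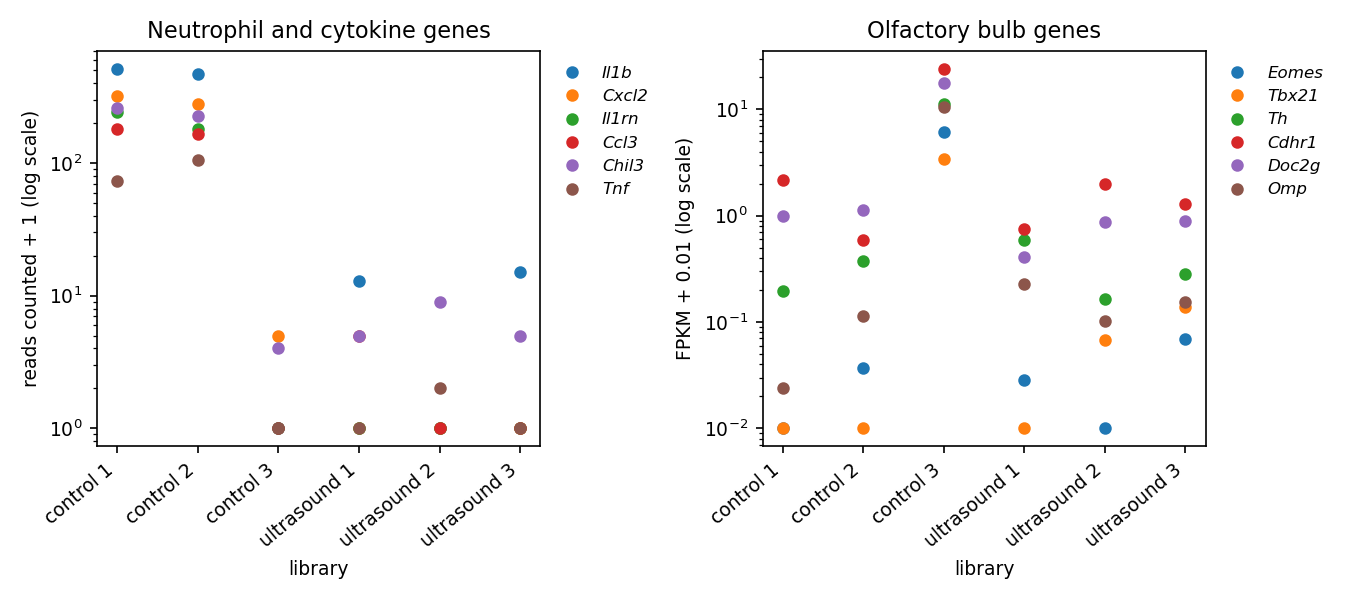
Left, reads counted plus 1 on a log scale for 6 neutrophil and cytokine genes in each of the 6 libraries, and right, FPKM plus 0.01 on a log scale for 6 olfactory bulb genes in the same libraries, with a colour per gene. Il1b had 514 and 472 counts in controls 1 and 2 and at most 14 in the other 4 libraries, and Omp was at 10.6 FPKM in control 3.

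Ion channel lists, which include sensors of mechanical force, did not pass with all 6 libraries. Of 17 tested mechanosensitive channel genes 9 were higher, with a median log2 fold change of 0.00 and an adjusted p of 0.955. Within that list Piezo1 had a log2 fold change of 0.42 (SE 0.29), Trpv4 0.51 (SE 0.70), the potassium channel Kcnk2 0.24 (SE 0.12) and Trpm7 -0.27 (SE 0.16). Voltage-gated calcium channels had a median of 0.06 (adjusted p = 0.590), with Cacna1g at -0.31 (SE 0.13) and Cacna1b at 0.32 (SE 0.15), and library medians of -0.06 to 0.00 in controls and 0.02 to 0.08 in ultrasound libraries (exact permutation p = 0.1). Voltage-gated sodium and potassium channels had a median of 0.01 (adjusted p = 0.378; adjusted p = 0.799 with an estimated correlation), though the list passed without ultrasound 2, with Kcnab1 at 0.57 (SE 0.15) and Scn4b at 0.81 (SE 0.28). GABA receptors had a median of 0.14 (adjusted p = 0.151), with Gabrb1 at 0.48 (SE 0.19). Activity-induced early genes had a median of -0.36 (adjusted p = 0.378), with Fos at 17.6 ± 13.3 FPKM in controls and 8.20 ± 4.95 FPKM in ultrasound libraries and Nr4a1 at 40.1 ± 20.1 and 22.3 ± 7.00 FPKM (SD, n = 3). By library, the list's median was 0.12, 0.88 and -0.59 in controls 1 to 3 and -0.21, -0.54 and 0.31 in ultrasound libraries 1 to 3. Control 3 lay below every ultrasound library, so the direction depended on the control. Neurotrophic factors and receptors had a median of 0.14 (adjusted p = 0.0661; adjusted p = 0.799 with an estimated correlation) and passed in camera on log2 CPM and at a mean FPKM of at least 1, with Vgf at 0.62 (SE 0.16), Ntrk2 at 0.25 (SE 0.14) and Bdnf at 0.67 (SE 0.37).

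Lists for neurons, glia and vessels were near 0 or varied between libraries. Excitatory cortical neuron genes had a median log2 fold change of 0.12 (adjusted p = 0.260), with the glutamate transporter Slc17a7 at 0.36 (SE 0.16) and Mef2c at 1.16 (SE 0.32). Inhibitory neuron genes had a median of -0.10 (adjusted p = 0.922), with Gad1 at -0.38 (SE 0.30) and Crh at -0.64 (SE 0.31). Astrocyte genes had a median of 0.04 (adjusted p = 0.378), with the water channel Aqp4 at 0.55 (SE 0.18) and Slc1a2 at 0.36 (SE 0.16). Oligodendrocyte and myelin genes had a median of 0.21 (adjusted p = 0.182), with Mbp at 0.08 (SE 0.25). Endothelial genes had a median of -0.01 (adjusted p = 0.922), with Cldn5 at -0.37 (SE 0.25). Pericyte and smooth muscle genes had -0.07 (adjusted p = 0.922), with Vtn at -0.31 (SE 0.29), and camera ranked these last 2 lists slightly upward. Fibroblast and meninges genes had a median of 0.25 (adjusted p = 0.151), with Dcn at 1.37 (SE 0.53). Blood genes had a median of 0.84 (adjusted p = 0.222), with Hbb-bs at 1.18 (SE 1.42). Thalamic genes had a median of -0.26 (adjusted p = 0.716), hippocampal genes 0.04 (adjusted p = 0.436) and hypothalamic genes 0.11 with a mean of -0.61 (adjusted p = 0.545).

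Stress, energy and disease lists other than the unfolded protein response did not pass in the main fit. Cytosolic heat shock genes had a median log2 fold change of 0.09 (adjusted p = 0.222), with Hspe1 at 0.33 (SE 0.16). Antioxidant and NRF2 target genes had a median of -0.05 (adjusted p = 0.576), with Gclm at -0.59 (SE 0.30). Autophagy and lysosome genes had a median of -0.06 (adjusted p = 0.260), with 14 of 17 lower and Map1lc3b at -0.59 (SE 0.38). Apoptosis genes had a median of -0.16 (adjusted p = 0.394), with Bcl2 at 0.46 (SE 0.16) and Casp9 at -0.46 (SE 0.23). Nuclear genes of oxidative phosphorylation had a median of 0.00 and a mean of -0.01 (adjusted p = 0.609), and mitochondrially encoded genes a median of 0.16 (adjusted p = 0.251). Ribosomal protein genes had a median of -0.08 (adjusted p = 0.129), with 19 of 27 lower. Axon growth and injury genes had a median of 0.16 (adjusted p = 0.111), with Map1b at 0.35 (SE 0.11) and Nefm at 0.34 (SE 0.16). Genes linked to amyotrophic lateral sclerosis had a median of 0.03 and a mean of -0.00 (adjusted p = 0.922), with the autophagy receptor Optn at -0.51 (SE 0.16) and Kif5a at 0.30 (SE 0.17). Sod1 itself averaged 36.0 ± 2.65 FPKM in controls and 34.3 ± 2.47 FPKM in ultrasound libraries (SD, n = 3), a log2 fold change of -0.03 (SE 0.13).

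Synaptic and adhesion terms of the annotation ranked highest without passing. Of 514 terms 0 had an adjusted p under 0.05 in camera, and 70 had an unadjusted p under 0.05, 61 of them higher with ultrasound and 9 lower. Cholinergic synapse with 89 tested genes, cell adhesion molecules with 85 and glutamatergic synapse with 98 shared the smallest adjusted p of 0.0961 with the broader cell adhesion term of 173 genes, and 0 terms passed with an estimated correlation. Without ultrasound 2, 10 terms passed.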

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

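The settings that left out pairs of libraries, some edgeR variants, camera on log2 CPM and the fry test in either direction were chosen after the data were seen. The limma fit of log2(FPKM + 0.5) had been named in advance as an alternative, and Phc3 had an adjusted p of 0.117 in that limma fit. The count of changed genes was 1 and became 0 in all 9 limma fits of FPKM values (pseudocounts 0.5, 0.1 and 1, median of ratios, TPM, quantile normalization, mitochondrial and haemoglobin genes left out, library weights, no trend and no robust step) and 0 at a mean FPKM of at least 5, where Phc3 was not tested. It was 2 with no filter and 29 in DESeq2, which left 59 adjusted p-values undefined. Leaving out 1 library gave 1 to 4 genes. Leaving out control 3 and ultrasound 2, the libraries richest in 18S, gave 8, and leaving out controls 1 and 2, which leaves a single control assumed to vary like the other libraries, gave 32. The count with an unadjusted p under 0.05 and at least a 2-fold change was 200 and became 68 in the limma fit with a pseudocount of 1 (146 in the limma fit with 0.5), 489 with no filter, 119 at a mean FPKM of at least 1, 28 at one of at least 5, and 626 without controls 1 and 2; the filter settings test other numbers of genes. The 8 lists past the threshold became 0 with an estimated correlation, 0 in fry and 0 in fry in either direction. With 1 library left out the count was 4 to 12, which included lists outside the 8. Without controls 1 and 2, control 3 was the only control. Its striatal median (0.93) lay above every ultrasound library (0.09 to 0.66). Its median of activity-induced early genes (-0.59) lay below every ultrasound library (-0.54 to 0.31). Both are the reverse of the difference between the full groups. The 0 terms past the threshold became 4 at a mean FPKM of at least 1, 3 at one of at least 5, 4 with library weights, 10 without control 3 and ultrasound 2, and 0 to 10 with 1 library left out. Except where the number of genes or libraries changed, the cause was not tested.

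No pairing of the libraries by replicate number was seen. Deviations from the group means correlated at -0.051, -0.054 and 0.052 between libraries of the same number, and control 2 correlated best with ultrasound 1 (0.2). These correlations cannot exclude a pairing that has little effect on expression beside the other differences between libraries. With the number as a block, 1 gene passed and 185 had an unadjusted p under 0.05 and at least a 2-fold change, with 8 lists and 0 terms, and the log2 fold change of Gfap was 0.025.

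Of 3099 values of 122 named genes under the alternatives, 3038 kept their direction and their side of the threshold, 9 lost the threshold (Phc3 in the limma fits), 14 gained it and 38 had the other sign, none of them past the threshold in either fit; the cause of these was not tested. With 1 library left out, the log2 fold change ranged from -1.824 to 0.686 for Calb2, -7.836 to 5.26 for Avp, -0.127 to 0.048 for Sod1, -0.183 to 0.317 for Gfap, -0.523 to 0.356 for Aif1, -1.792 to 1.09 for Chat, -0.594 to 0.038 for Gad1, -0.186 to 0.28 for Mbp, -0.04 to 0.714 for Ermn and -0.582 to 0.861 for Trpv4. Gfap was at 0.031 with median of ratios, 0.007 with quantile normalization, 0.007 without mitochondrial and haemoglobin genes and 0.118 with library weights, where Chat was at 0.118 and Mbp at -0.005, and Chat was at 0.011 with quantile normalization. Without control 3 and ultrasound 2, Calb2 was at 0.701, Gfap 0.393, Aif1 0.051, Chat 1.526 and Gad1 0.147. Without controls 1 and 2, Kcnj8 was at 0.243, Hbb-bs -0.163, Hbb-bt -0.212, Zbtb20 -0.004, Dusp1 0.276, Ccl3 3.491, Chil3 0.634, Ifit3 -0.03 and Fos 0.514. Some of these values rest on counts in 1 or 2 libraries: Avp had 68 counts in control 3, 12 in ultrasound 2 and 0 in the other 4, and Ccl3 had 180 and 166 in controls 1 and 2 and, without them, only 4 in ultrasound 1.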

Other observations

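A few antigen presentation, survival and mitochondrial genes, picked after their values were seen, differed between libraries without passing the threshold. The class II genes H2-Ab1 and H2-Aa averaged 0.327 ± 0.272 and 0.367 ± 0.355 FPKM in controls and 0.973 ± 0.186 and 0.882 ± 0.150 FPKM in ultrasound libraries (SD, n = 3), with log2 fold changes of 1.60 (SE 0.88) and 1.29 (SE 0.72) that did not pass. Their list was mixed, with 7 of 12 members lower, among them B2m at -0.30 (SE 0.17) and H2-K1 at -0.20 (SE 0.22). Cd4, which microglia and T cells both express, had a log2 fold change of 1.37 (SE 0.54) and did not pass. Optn was lower in each ultrasound library than in each control, at 4.75 ± 0.211 against 3.25 ± 0.220 FPKM, and Bcl2 was higher in each, at 1.83 ± 0.12 against 2.45 ± 0.13 FPKM, also without passing, while 13 of 17 apoptosis genes were lower. Mitochondrial-like pseudogenes on chromosome 1, between 24650616 and 24655278 in the table, took 0.11% of the counts in ultrasound 1 and 1.19% to 1.91% in the other 5 libraries, while mt-Atp6 ranged from 828 FPKM in ultrasound 2 to 7893 FPKM in ultrasound 1.

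The tests of other splits of the libraries and of the genes near Phc3 were set before their results were seen, and the remaining tests of explanations were chosen after. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For changed genes, 7 of the 10 splits gave at least the real count of 1, and the highest other count was 4. For genes with an unadjusted p under 0.05 and at least a 2-fold change, 5 splits gave at least 200, with 294 as the highest other count. For lists, 4 splits gave at least 8, with 15 as the highest other count. For terms the real count was 0, which all 10 splits reach by construction, so this comparison tests nothing, and the highest other count was 23.

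Phc3 was higher in each of the 3 ultrasound libraries than in any control. Leaving out any library kept the edgeR adjusted p at or below 0.0403, which argues against 1 library carrying the difference. The summed CPM of the paralogs Phc1 and Phc2 and of the overlapping gene fell by 6.2% of the gain in Phc3, which argues against reads moved from Phc1 or Phc2. The overlapping gene had a mean of 0 CPM in both groups, so it had no reads to lose. Reads left uncounted as ambiguous would not show in this comparison. Of 22 tested genes within 2 Mb of Phc3, 1 (4.55%, exact 95% interval 0.12% to 22.8%) had an unadjusted p under 0.05, so a haplotype block shared with its neighbours remains open, since the interval reaches above the 20% set in advance. An effect of ultrasound on Phc3 is a hypothesis that stays open beside a variant that acts on Phc3 alone and beside chance. With the real split included, 7 of the 10 splits of the libraries gave at least 1 changed gene, and the limma fits did not pass Phc3.

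Many neutrophil transcripts and some cytokine transcripts were higher in controls 1 and 2 than in the other 4 libraries. Il1b had 514 and 472 counts in controls 1 and 2, 0 in control 3 and 12, 0 and 14 in the ultrasound libraries, and of 20 neutrophil markers with at least 30 counts, 14 were higher in controls 1 and 2 than in the other 4, while Ngp, Camp and Ltf were highest in ultrasound 2. Among members of the fixed lists with at least 30 counts, the same held for 8 of 20 inflammatory cytokines and NF-kB targets and 3 of 10 anti-inflammatory mediators, and not for Il6 and Ptgs2, so the pattern covers a part of these lists. The highest haemoglobin share of controls 1 and 2 was 11% of the median of the other 4, a comparison and cutoff chosen after the values were seen. Ultrasound 3 was as low as controls 1 and 2, at 0.001% of counts, and the other 3 libraries had more haemoglobin and little or no Il1b, which argues against blood left in the tissue. Il1b in the lower of controls 1 and 2 would still reach 300 counts at the depth of the shallowest library, which argues against depth. All 3 controls lay above all 3 ultrasound libraries for 4 of the 20 markers, so most markers did not separate the groups. A lowering by ultrasound that acts only where these transcripts are high cannot be told apart from a state of 2 control mice. Infiltrating neutrophils in those 2 controls are a candidate source, found and tested on the same data. Some of the 20 markers reached 30 counts only through these 2 controls, as Clec4d did with 68 and 50 counts there and 0 elsewhere. Other neutrophil markers were nearly absent. Ly6g had 4 counts in control 2 and 0 elsewhere, Mpo had 5 in ultrasound 1 and 0 elsewhere, and Elane had 0 in every library.

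Transcripts of neighbouring brain regions differed between libraries. The 14 striatal genes moved together within groups, with an estimated correlation of 0.885, as a varying share of striatal tissue would give. The other lists with the highest values were blood (0.93), myelin (0.857) and activity-induced early genes (0.796). A high correlation therefore does not identify its source. Of 15 textbook olfactory bulb genes other than those that prompted the comparison, 14 were highest in control 3, among them Scgn, Dlx2 and Meis2. The exact 95% interval was 68.1% to 99.8%, where chance gives 16.7% for independent genes. These genes were read from the same libraries and can move together, so the interval does not measure chance. Olfactory bulb tissue in control 3 may be their source. The count of 14 does not separate it from other neighbouring tissue, since control 3 also had the highest striatal median (0.93). Dlx1, also in this set, is a member of the fixed inhibitory neuron list. An effect of ultrasound on striatal genes stays open, with an exact permutation p of 0.5 for the library medians.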
